A study of Homo sapiens with 6 samples.

How the data were processed

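RNA was measured by sequencing in 6 samples of primary human aortic smooth muscle cells, 3 given scrambled RNA (a control RNA without an intended target) and 3 given small interfering RNA (siRNA, short RNA that directs the cutting of a matching transcript) against elastin, the product of ELN. Per the labels' protocols, cells in medium with 10% serum received the RNA at 50 nM with a lipid reagent for 6 hours and were collected after 72 hours, and libraries were made with a kit for messenger RNA. The labels do not say whether the samples of a group were separate cultures or came from separate donors, so p-values measure the spread between these samples, which may be technical. The sequence of the siRNA, and whether 1 sequence or a mixture was used, is not given in the sources used here.

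The deposited table holds expected counts (estimated reads per gene, not normalized), with 24796 lines for 22584 gene symbols. The submitters' processing notes name Bowtie2, the hg19 genome build and DESeq2 without versions or roles. The counting tool, the gene annotation and any use of strand are not given in the sources used here. Of the values, 68.8% were whole within a tolerance of 0.001 and the rest were fractional, as where reads are divided between features, and no listed gene had a total under 10 over the 6 libraries. Symbols on more than 1 line (1182, for example the copies of 7SK) carried identical values on each line and were used once. Reads from a gene and a near-identical copy, an overlapping gene or an antisense gene cannot be told apart in such a table. Coordinates are those of the deposited table. Stop minus start equalled the GENCODE 29 gene length for 11808 of the 16904 single-locus symbols compared, so start and stop are not both inclusive there. The stop was taken to be 1 past the gene end, and the end printed is the stop minus 1. Positions themselves were not compared, so an offset of the start was not excluded.

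Expected counts were rounded to whole numbers before testing. Library totals were 24498268, 29939896 and 30605839 for scrambled replicates 1 to 3 and 26047378, 25186969 and 28669062 for siELN replicates 1 to 3. With R 4.3.3 and edgeR 4.0.16, genes were kept by filterByExpr (18428 tested, 4156 dropped), scaled by the trimmed mean of M values (TMM), and tested by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) of siELN against scrambled, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the log2 fold change divided by the square root of the F statistic. CPM values are counts per 1000000 of the TMM-scaled library size. In counts simulated from these libraries, with 50 genes changed at each size among 18204 tested, the test recovered 22% of genes changed 1.2-fold, 72% changed 1.5-fold, 84% changed 2-fold and 94% changed 4-fold, and called 3 of 18004 unchanged genes. In the real comparison 53.4% of genes were called, and the adjusted threshold depends on that share. The simulated shares and false calls therefore do not carry over to it. The smallest p an exact permutation test can give with 3 against 3 libraries is 0.1.

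The 25 gene lists, the design and the rule for named genes were fixed before the data were examined. Listed symbols were matched through older names in a RefSeq gene table. The 23 lists with at least 5 tested members were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Named genes were ELN, then the 6 risen and the 6 fallen genes with the largest log2 fold change among those called with a mean CPM of at least 5 and no overlap between groups, then up to 2 called members per list with the smallest adjusted p. Genes named outside this rule are said to be chosen after their values were seen. Genes of sex-specific expression were not named, and some genes that the rule takes are not reported here.

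The 3′ untranslated regions (UTRs) of the basic set of GENCODE 29 (GRCh38), the longest per gene, were searched for 7-base sequences. Of the 12081 tested genes with a mean CPM of at least 5, 9483 were protein-coding there by symbol, and 9396 had a 3′ UTR of at least 50 bases and were scanned. For each of 16148 sequences present in at least 50 genes, the log2 fold changes of genes with and without it were compared in a regression on 3′ UTR length and GC content. With fold changes permuted over genes, the most extreme z values were −3.94 and 4.45, and a planted sequence ranked 1. Gene lengths and GC content came from the same annotation, and 74.9% of the deposited symbols were in it. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

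Alternatives were other scaling factors (RLE, or library size alone), no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, effect-size limits, camera with the correlation estimated from the data, the rotation test fry, and adjustment over the list alone. A run without the genes whose 3′ UTR holds GCCAAGT was added after the data were seen. No library was left out of the comparison, and no pair of libraries in a group agreed within sampling noise (chi-square per gene 3.16 to 8.74 over pairs).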

Results

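Gene expression was measured in human aortic smooth muscle cells 72 hours after treatment with scrambled RNA (3 libraries) or with siRNA against ELN (siELN, 3 libraries). The question was which other genes differ when the RNA for elastin, the main protein of elastic fibres, is lowered. Elastin protein was not measured here. Library totals ran from 24498268 to 30605839 counts. The first principal component held 74.7% of the variance and separated the groups. Log2 fold changes are siELN against scrambled and are given ± SE, and CPM means ± SD.

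ELN, which encodes the soluble precursor of elastin (hg19 chromosome 7, 73442119 to 73484237, plus strand), was lower in each siELN library than in each scrambled library. It stood at 12.6, 11.6 and 14.1 CPM in scrambled replicates 1 to 3 and at 1.03, 0.594 and 0.872 CPM in siELN replicates 1 to 3, which were 309, 347 and 427 counts against 27, 15 and 25. The mean fell from 12.8 ± 1.29 to 0.832 ± 0.221 CPM (SD, n = 3 each), a log2 fold change of −3.93 ± 0.17 (SE; adjusted p = 4.83e-12, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

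**Figure D1:**
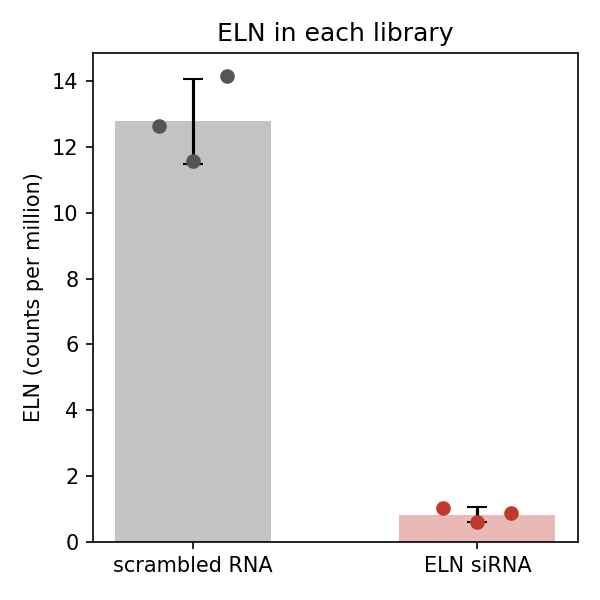
ELN in CPM (vertical axis) in each library of the 2 groups. Points are libraries, bars the mean and error bars the SD (n = 3), and the siELN libraries lay between 0.594 and 1.03 CPM and the scrambled libraries between 11.6 and 14.1.

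Many genes differed in expression between the groups, in both directions. Of 18428 genes, 4849 rose and 4989 fell in siELN cells (53.4% called; edgeR quasi-likelihood test), and 752 rose and 1248 fell at least 2-fold. Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise was that of LIPH, a phospholipase that makes lysophosphatidic acid, from 0.361 ± 0.147 to 14.2 ± 1.44 CPM (SD, n = 3), a log2 fold change of 5.26 ± 0.19 (SE; adjusted p = 7.63e-13, edgeR quasi-likelihood test). TNFSF4 (OX40 ligand) rose by 2.93 ± 0.11 on the log2 scale. PDGFB, a growth factor for smooth muscle cells, rose by 2.74 ± 0.17 and GDF15, a stress-induced secreted factor, by 2.64 ± 0.05. OR52K3P (3.59 ± 0.14), an olfactory receptor pseudogene, and RP11-318A15.2 (2.63 ± 0.12), a locus without an official symbol, completed the 6 largest rises and are uncertain because reads of related or overlapping genes could be counted there. The largest falls under the same limits, besides ELN, were those of DEPDC1 (−4.70 ± 0.16), TOP2A (−4.10 ± 0.11), CCNA2 (−3.98 ± 0.14), LCP1 (−3.89 ± 0.13) and KIF20A (−3.81 ± 0.17). TOP2A, CCNA2 and KIF20A act in cell division, and LCP1 encodes an actin-bundling protein. Common dispersion gave a biological coefficient of variation of 5.85%, and 10946 genes (59.4%) had no overlap between the groups, where chance gives 10%.

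A 7-base sequence, GCCAAGT, occurred in the annotated 3′ UTR of 13 of the 54 reported named genes that were searched, ELN among them. It was found in DEPDC1, TOP2A, CCNA2, LCP1, TIMP3, LUM, OAS3, HDAC1, INHBA, TEK, TGFBI and CSF1R, and each of these was lower in siELN cells. Named genes were picked for the size or certainty of their change, and GCCAAGT for lower fold changes in these same data. That each of them was lower is therefore no independent test. Of the 9396 genes scanned, 1051 (11.2%) held the sequence, of which 607 fell, 182 rose and 262 were not called (edgeR quasi-likelihood test). The share that fell was 57.8% of genes with the sequence and 28.3% of those without.

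**Figure D2:**
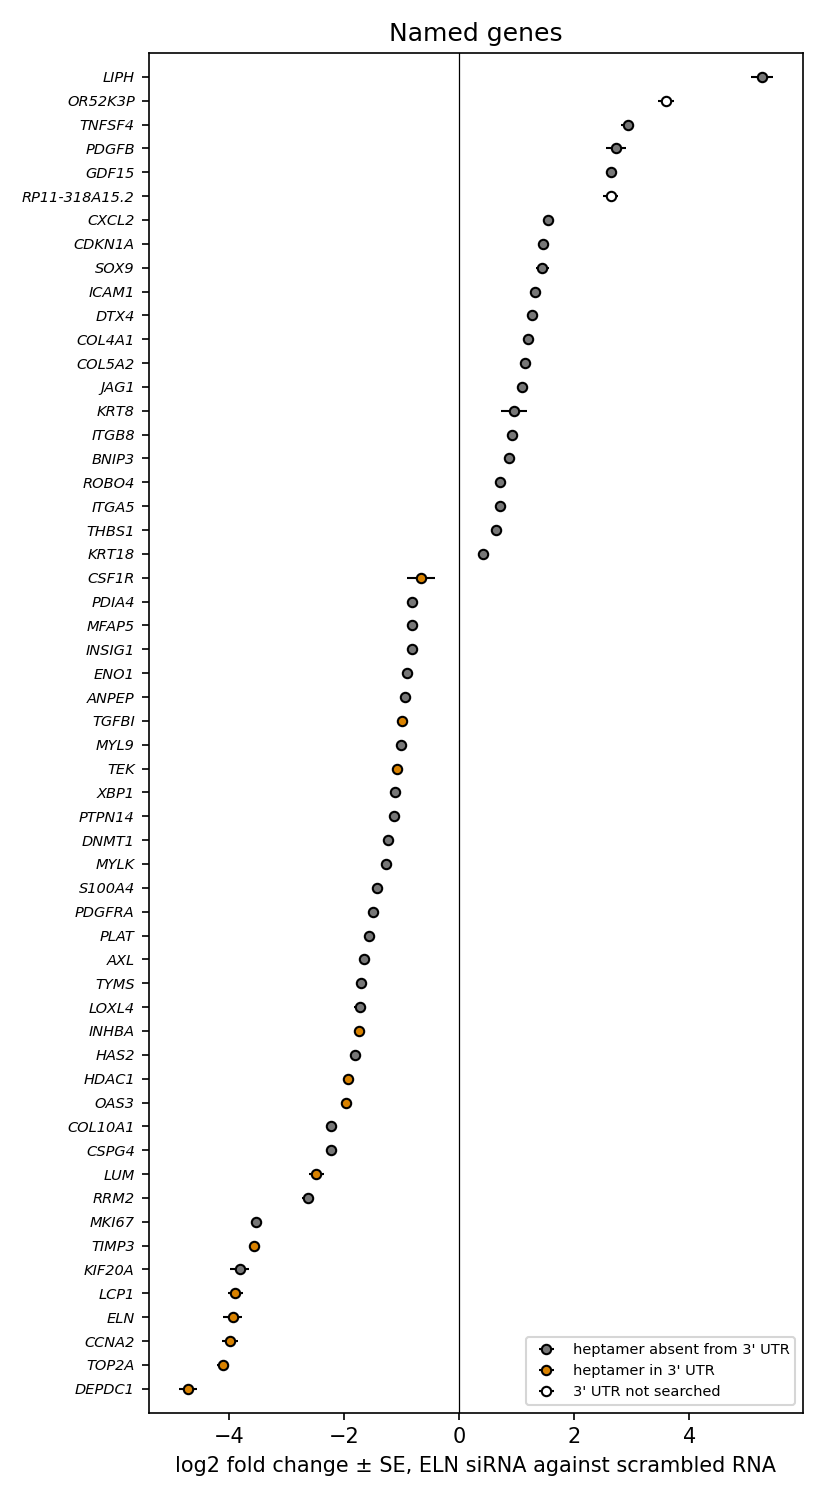
Log2 fold change of the named genes (horizontal axis, siELN against scrambled, error bars SE) in order of change. Filled orange points are genes whose annotated 3′ UTR holds GCCAAGT, grey points genes without it, and white points genes not searched. The 13 orange points all lie below 0, and the sequence was picked for lower fold changes in these same data.

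Genes of cell division fell together. All 24 mitosis and G2/M genes were lower (adjusted over the list alone, 24 lower), with a median log2 fold change of −3.38. The proliferation marker MKI67 fell from 169 ± 23.04 to 14.7 ± 1.23 CPM (SD, n = 3), a log2 fold change of −3.53 ± 0.09, and TOP2A, the DNA topoisomerase of dividing cells, by 4.10 on the log2 scale. Of 22 DNA replication and S phase genes, 21 fell and 1 rose (adjusted over the list alone, 21 and 1), with a median of −1.85. RRM2 (−2.62 ± 0.10) and TYMS (−1.69 ± 0.07), which supply deoxynucleotides, fell, and the riser was CCNE1 (0.44), named after its value was seen. Camera called both lists lower, with adjusted p = 4.58e-78 for mitosis (adjusted p = 0.0566 with an estimated correlation) and 7.48e-25 for S phase (adjusted p = 0.0873 with an estimated correlation).

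Of 20 p53 targets, 14 rose, 3 fell and 3 were not called (adjusted over the list alone, 14 and 3), with a median log2 fold change of 0.93. CDKN1A, the inhibitor of cyclin-dependent kinases p21, rose from 586 ± 18.8 to 1611 ± 63.5 CPM (SD, n = 3), a log2 fold change of 1.46 ± 0.04, and GDF15 from 59.0 ± 1.29 to 368 ± 15.4 CPM. Camera gave adjusted p = 7.97e-12, and of the 23 tested lists this was the 1 called with an estimated correlation (adjusted p = 0.0339 with an estimated correlation). The members that fell were TP53I3 (−0.89), RRM2B (−0.81), whose 3′ UTR holds GCCAAGT, and XPC (−0.46), a DNA repair gene. BTG2 (1.69) and TP53INP1 (1.03), whose 3′ UTRs hold it too, rose. MDM2, the ubiquitin ligase of p53, had a log2 fold change of 0.02 and was not called. These 6 were named after their values were seen.

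Matrix genes moved in both directions. Of 31 collagen and collagen processing genes, 20 rose, 3 fell and 8 were not called (adjusted over the list alone, 20 and 4, median 0.30). COL4A1, a basement membrane collagen, rose from 184 ± 4.28 to 423 ± 4.31 CPM (SD, n = 3; adjusted p = 6.78e-13, edgeR quasi-likelihood test) and COL5A2 by 1.15 ± 0.05 on the log2 scale. Of 25 elastic fibre assembly genes other than ELN, 14 fell, 7 rose and 4 were not called (adjusted over the list alone, 15 and 7, median −0.30), with LOXL4, a lysyl oxidase (−1.71 ± 0.10), and MFAP5, a microfibril protein (−0.82 ± 0.05), lower. Camera gave adjusted p = 7.03e-06 for collagens (adjusted p = 0.141 with an estimated correlation) and 0.0341 for elastic fibre genes (adjusted p = 0.236 with an estimated correlation), and the second call ended under a filter of 1 CPM in 3 libraries (0.0548).

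Of 30 matrix proteases and inhibitors, 13 rose, 8 fell and 9 were not called (adjusted over the list alone, 13 and 8). TIMP3, the matrix-bound inhibitor of metalloproteinases, fell from 4360 ± 107 to 370.1 ± 45.1 CPM (SD, n = 3; −3.56 ± 0.07; adjusted p = 1.07e-15, edgeR quasi-likelihood test) and PLAT, tissue plasminogen activator, by 1.56 on the log2 scale. Of 28 matrix glycoproteins and proteoglycans, 8 rose, 11 fell and 9 were not called (adjusted over the list alone, 8 and 11), with THBS1 higher (0.64 ± 0.03) and the hyaluronan synthase HAS2 lower (−1.80 ± 0.06). Of 16 integrins, 8 rose, 6 fell and 2 were not called (adjusted over the list alone, 9 and 6), with ITGB8 (0.92 ± 0.06) and ITGA5 (0.71 ± 0.04) higher. Camera called none of these 3 lists (adjusted p = 0.314, 0.827 and 0.0615). Proteases had a median of 0.06 against a mean of −0.03 and a camera direction of down, and integrins a median of 0.15 against a mean of −0.01 and a direction of up. Integrins were called with the replicate number as a block (adjusted p = 0.0271) and without siELN replicate 1 (0.0217) or 3 (0.0424), and not with an estimated correlation (adjusted p = 0.236 with an estimated correlation). Over all alternatives the adjusted p for integrins ran from 0.00135 (fry) to 0.290 (camera).

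Smooth muscle genes moved in both directions. Of 20 contractile genes, 5 rose, 8 fell and 7 were not called (adjusted over the list alone, 5 and 8). MYLK, the kinase of myosin light chain, fell from 246 ± 5.84 to 103 ± 3.41 CPM (SD, n = 3; −1.26 ± 0.05) and MYL9 by 1.01 on the log2 scale. MYOCD, a coactivator of smooth muscle genes (1.16), and MYH11, smooth muscle myosin heavy chain (1.47, at a mean of 2.32 CPM), rose, and were named after their values were seen. Also named after their values were seen, ACTA2 (0.20) and TAGLN (0.13) rose less, and CNN1 (−0.23), MKL1 (−0.54) and MKL2 (−0.88) fell. Camera did not call the list (adjusted p = 0.295, median 0.01, mean −0.07, direction down). Of 14 genes of the synthetic or modulated state, 3 rose, 7 fell and 4 were not called (adjusted over the list alone, 3 and 7). PDGFRA (−1.50 ± 0.04) and S100A4 (−1.42 ± 0.08) fell while PDGFB rose, and camera called the list lower (adjusted p = 0.0153; adjusted p = 0.141 with an estimated correlation). Of 13 osteochondrogenic genes, 2 rose, 5 fell and 6 were not called (adjusted over the list alone, 2 and 5). The transcription factor SOX9 rose (1.45 ± 0.11) and COL10A1 fell (−2.22 ± 0.08), and the list was not called (adjusted p = 0.118, median 0.04, mean −0.28, direction down).

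Among markers of other cell types, adventitial fibroblast and pericyte lists were called lower. Of 11 fibroblast markers, 2 rose, 5 fell and 4 were not called (adjusted over the list alone, 2 and 5, camera adjusted p = 0.0153, and adjusted p = 0.236 with an estimated correlation), with LUM lower (−2.47 ± 0.14). LUM, PDGFRA and MFAP5, the largest falls of this list, are among 9 of 470 tested members that belong to more than 1 list. The fibroblast call is therefore not separate from those of the synthetic state and elastic fibre lists. Of 7 pericyte markers, 2 rose, 3 fell and 2 were not called (adjusted over the list alone, 2 and 3, camera adjusted p = 0.0341, and adjusted p = 0.236 with an estimated correlation; 0.0548 under a filter of 1 CPM in 3 libraries), with CSPG4 (−2.23 ± 0.09) and ANPEP (−0.95 ± 0.05) lower. Of 8 endothelial markers, 3 rose, 3 fell and 2 were not called (adjusted over the list alone, 3 and 3, camera adjusted p = 0.908), with TEK lower (−1.07 ± 0.07) and ROBO4 higher (0.71 ± 0.07). Leukocyte and epithelial lists had 2 and 4 tested members and were not tested as lists (adjusted over the list alone, 1 fell in the first, and 2 rose and 1 fell in the second, as over all genes). CSF1R was lower (−0.66 ± 0.24; 1.79 to 1.15 CPM), and its call ended without scrambled replicate 2 or 3 or siELN replicate 3 (adjusted p = 0.0988, 0.0741 and 0.119) and in DESeq2 (0.0961). KRT8 (0.96 ± 0.23) and KRT18 (0.42 ± 0.09) were higher, and are uncertain because their loci overlap in the table.

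Inflammatory and interferon-stimulated genes moved in both directions. Of 28 NF-kB and cytokine genes, 20 rose, 5 fell and 3 were not called (adjusted over the list alone, 20 and 5, with a median of 0.27), with the chemokine CXCL2 (1.54 ± 0.06) and the adhesion molecule ICAM1 (1.33 ± 0.04) higher. Camera gave adjusted p = 5.09e-06 (adjusted p = 0.141 with an estimated correlation). Of 28 interferon-stimulated genes, 2 rose, 14 fell and 12 were not called (adjusted over the list alone, 2 and 14, median −0.42), with OAS3 lower (−1.97 ± 0.09). Camera gave adjusted p = 0.0208 (adjusted p = 0.450 with an estimated correlation), and 0.0997 without the genes whose 3′ UTR holds GCCAAGT, which left 23 members with a median of −0.36.

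Of 16 NOTCH pathway genes, 11 rose, 3 fell and 2 were not called (adjusted over the list alone, 11 and 3, median 0.44). The ligand JAG1 (1.09 ± 0.07) and DTX4 (1.27 ± 0.07) rose, and camera gave adjusted p = 0.0153 (adjusted p = 0.141 with an estimated correlation). Of 24 TGF-beta genes, 14 rose, 5 fell and 5 were not called (adjusted over the list alone, 14 and 5, median 0.22, camera direction up with adjusted p = 0.111, and up with 0.000511 without the 5 members and other genes whose 3′ UTR holds GCCAAGT). The 5 members had a median of −0.94 and the others 0.24. Because GCCAAGT was picked for lower fold changes in these same data, the second value is no independent test. TGFB2 (2.30) and ID1 (1.71), named after their values were seen, rose. INHBA, a subunit of activin, fell from 1648 ± 18.3 to 497 ± 41.7 CPM (SD, n = 3; −1.73 ± 0.05) and TGFBI by 0.99 on the log2 scale. Of 23 YAP/TAZ targets, 10 rose, 10 fell and 3 were not called (adjusted over the list alone, 10 and 10, camera adjusted p = 0.699), with AXL (−1.64 ± 0.05) and PTPN14 (−1.13 ± 0.05) lower.

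Of 20 hypoxia and glycolysis genes, 14 rose, 2 fell and 4 were not called (adjusted over the list alone, 14 and 2, median 0.32, camera adjusted p = 0.00138, and adjusted p = 0.273 with an estimated correlation). BNIP3 rose (0.88 ± 0.05), while the glycolytic enzyme ENO1 fell from 876 ± 3.84 to 469 ± 22.2 CPM (SD, n = 3; −0.90 ± 0.04). Of 23 cholesterol synthesis genes, 12 fell, 3 rose and 8 were not called (adjusted over the list alone, 12 and 3, camera adjusted p = 0.0926, and 0.0436 without the genes whose 3′ UTR holds GCCAAGT, none of which is in this list), with INSIG1 lower (−0.82 ± 0.07). Of 23 genes of the unfolded protein and integrated stress response, 10 fell, 4 rose and 9 were not called (adjusted over the list alone, 10 and 4, camera adjusted p = 0.217), with XBP1 (−1.11 ± 0.05) and PDIA4 (−0.81 ± 0.05) lower. Of 20 enzymes of DNA methylation and histone acetylation, 11 rose, 5 fell and 4 were not called (adjusted over the list alone, 11 and 5, camera adjusted p = 0.844, median 0.18, mean 0.00, direction down). HDAC1 (−1.94 ± 0.06) and DNMT1, the maintenance methyltransferase (−1.23 ± 0.06), fell.

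**Figure D3:**
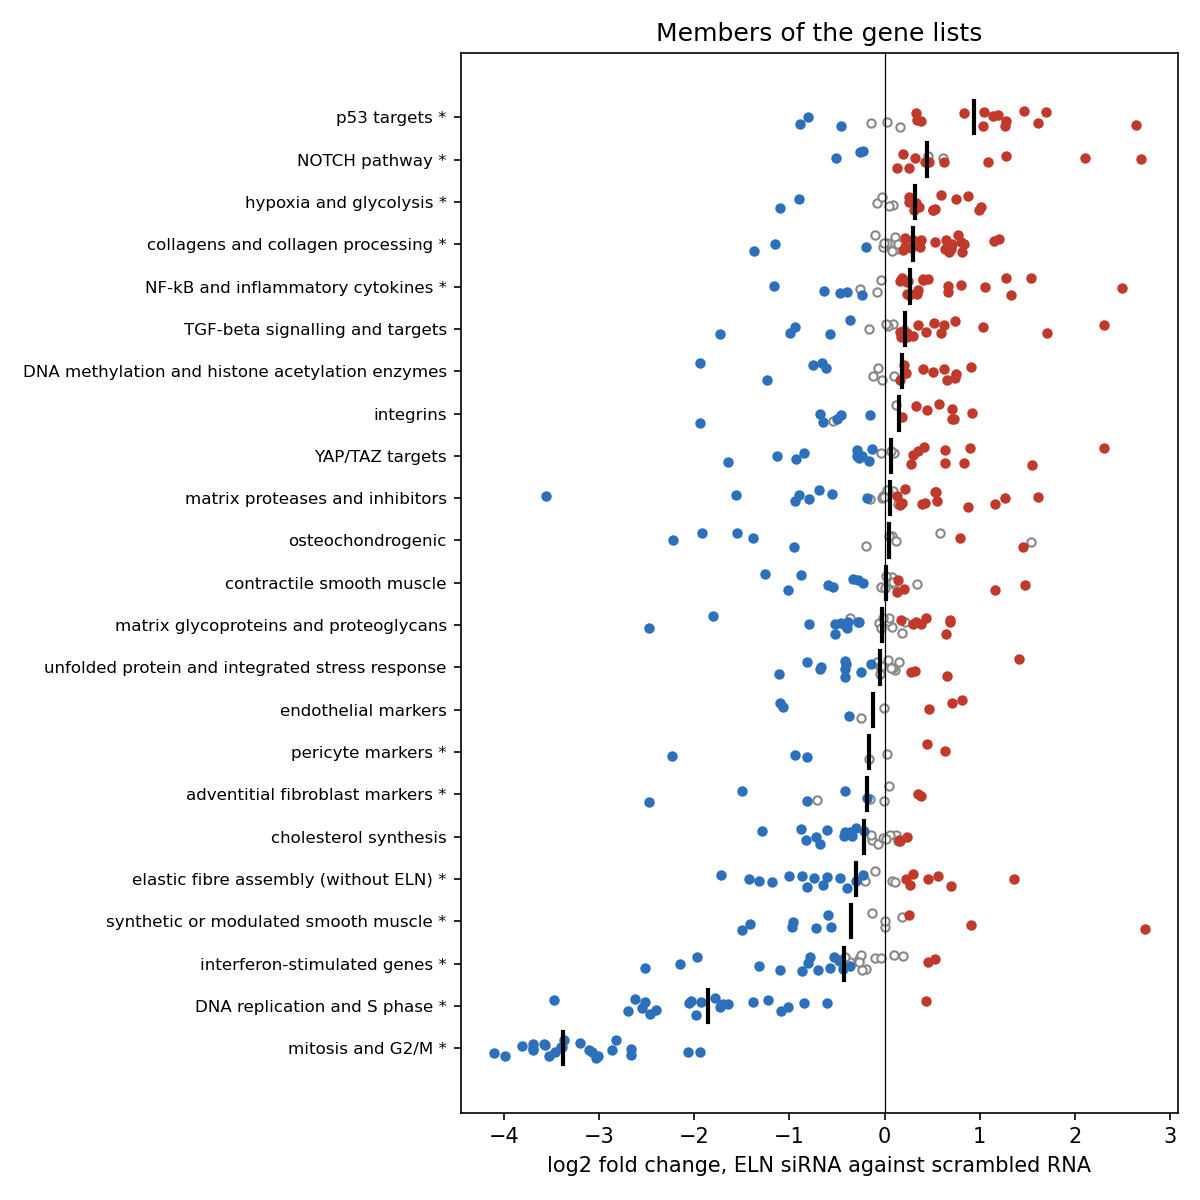
Log2 fold change (horizontal axis, siELN against scrambled) of each tested member of the 23 tested gene lists, ordered by median. Red points rose, blue points fell, open points were not called (edgeR quasi-likelihood test), black bars are medians, and stars mark the 12 lists called by camera. The mitosis list lies lowest, at a median of −3.38, and the p53 targets highest, at 0.93.

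The groups had overlapping total counts (exact permutation p = 0.5, two-sided), while some gene classes took different shares of them. Ribosomal protein genes took 1.26 ± 0.009% of counts in scrambled and 1.07 ± 0.018% in siELN libraries, and replication-dependent histone genes 0.0111 ± 0.0002% and 0.0193 ± 0.0005% (SD, n = 3 each). Both classes were taken by name, and the histone class includes pseudogene symbols. The 50 most abundant genes took 21.3 ± 0.18% and 22.0 ± 0.04%, and the most abundant gene 1.47 ± 0.04% and 1.79 ± 0.21%. Mitochondrial ribosomal RNA took 0.740 ± 0.018% and 0.696 ± 0.003%. For these 5 shares the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. All mitochondrially encoded genes together took 4.71 ± 0.23% and 4.499 ± 0.23% (exact permutation p = 0.4).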

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

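The run without the genes whose 3′ UTR holds GCCAAGT was chosen after the data were seen; the other alternatives were planned. Over the alternatives no called gene list or named gene changed direction. ELN stayed called, with log2 fold changes from −3.74 to −4.10. Against 4849 and 4989 of 18428 tested genes, calls stood at 4846 higher and 4990 lower with RLE factors, 4993 and 4869 with library sizes alone, 4236 and 4552 of 20832 tested in DESeq2, 4894 and 5051 of 22584 without a filter, 4819 and 4993 in limma-voom, 4606 and 4270 without the GCCAAGT genes, and 4189 to 4768 higher and 4538 to 4856 lower with 1 library left out. At least 1.5-fold, 1882 rose and 2498 fell, and at least 2-fold, 752 and 1248. Of the other 55 named genes reported, 54 kept their call under each alternative that tested them; CSF1R, near 1 CPM, did not (adjusted p up to 0.119).

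With the correlation estimated from the data, camera called p53 targets alone. The other lists had adjusted p = 0.0566 (mitosis), 0.0873 (S phase), 0.141 (synthetic state, collagens, NOTCH, NF-kB), 0.236 (elastic fibre, adventitial fibroblast, pericyte), 0.273 (hypoxia) and 0.450 (interferon). The estimates for p53 targets (−0.012), synthetic state (−0.035) and NOTCH (−0.0082) were below the preset 0.01. For synthetic state and NOTCH the unadjusted camera p still rose, from 0.00591 to 0.0430 and from 0.00503 to 0.0396. A higher correlation therefore does not account for these 2 lost calls. Fry, which tests whether a list moves on balance 1 way without comparing it with other genes, also called integrins (0.00135) and TGF-beta (0.00131) upward. It called contractile (0.00497), glycoproteins (0.00763), proteases (0.00292), cholesterol (0.000885), stress response (0.00494), osteochondrogenic (0.000885) and DNA methylation (0.0152) lists downward. For proteases (13 rose, 8 fell) and DNA methylation (11 rose, 5 fell) that direction goes against the count of called members. A filter of 1 CPM in 3 libraries moved elastic fibre and pericyte lists to 0.0548, and 1 library left out moved integrins to between 0.0217 and 0.0842. Without the GCCAAGT genes the interferon list was at 0.0997 (5 of 28 members left out, median −0.42 before and −0.36 after), TGF-beta, upward, at 0.000511 (5 of 24 left out, INHBA and TGFBI among them) and cholesterol at 0.0436 (no member left out, so that only the genes it is compared with changed). As GCCAAGT was picked for lower fold changes in these same data, these values are no independent tests. For the filter and the left-out library the cause was not tested.

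The replicate numbers were not treated as pairing, because the labels do not give a shared donor, day or batch. Over all tested genes, deviations of same-numbered libraries correlated at 0.101, 0.036 and 0.124. These values were low but above those of all other pairs, the highest of which was 0.0058. In the 5236 genes with a mean log2 CPM above 5, each library again correlated best with its own number, more strongly (0.311, 0.232 and 0.301). Both are a hint from the data and not from the design. With the replicate block, calls were 5149 and 5280, integrins were called (0.0271), and no other list or named gene changed its call.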

Other observations

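The gene groups in the next paragraph, the search for 7-base sequences, the comparison by coding sequence, the comparison by following base, the cell-cycle tests without the sequence (in the 3′ UTR or in any transcript) and after a GC and length trend, and the question of a second reagent were tests chosen only after the gene changes were seen, and those by coding sequence and following base after the sequence was found.

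Of 80 ribosomal protein genes tested, taken by name, 57 fell, 2 rose and 21 were not called (edgeR quasi-likelihood test; median log2 fold change −0.21, and −0.20 with library sizes alone). RPL22L1 (−1.82) and RPL29 (293 to 147 CPM) were among those that fell. Such genes have many processed pseudogenes, so single members are uncertain. Of 36 tested genes with symbols of replication-dependent histone genes, 16 rose, 2 fell and 18 were not called. Taken by name, they include pseudogene symbols, such as HIST1H1PS1 (counted as risen, 0.0493 to 0.435 CPM) and HIST2H3PS2 (not called), and many stood under 1 CPM. HIST1H2AC rose from 17.2 to 61.0 CPM and HIST1H2BC from 1.59 to 6.61 CPM, and HIST1H2BK, the most abundant of them in scrambled cells, fell (−0.80). These are near-identical copies, and the kit selects polyadenylated RNA, of which histone messages usually hold little. Of 16 targets of the antioxidant regulator NRF2, 9 rose, 4 fell and 3 were not called, with HMOX1 (1.53), SLC7A11 (1.78) and FTH1 (0.53) higher and TXNRD1 (−0.32) lower.

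Among 16148 7-base sequences, GCCAAGT in the 3′ UTR went with the most negative fold changes (z = −23.4, against 4.85 for the most positive sequence). The median was −0.30 over 1051 genes with it and 0.05 over 8345 without. The sequence was in 20.4% of scanned genes called lower, against 11.2% of all scanned genes. It was in 34.9% of those that fell at least 2-fold against 8.33% of those that rose as much. It lies in 15 of 15 ELN transcripts, on GRCh38 chromosome 7 in exon 17 (74051974 to 74051980, coding), exon 21 (74056704 to 74056710, coding) and the untranslated part of exon 33 (74068873 to 74068879) of 1 of them. Of all sequences scanned, 5.99% lie in all 15 transcripts, the most positive one (TGGTGCT) among them. An effect of composition alike in all parts of a transcript is argued against, since matches in the coding sequence alone went with a difference of −0.25 ± 0.02 and matches in the 3′ UTR with −0.51 ± 0.02 (SE), although the first is not 0. A candidate explanation is that the siRNA lowered unintended transcripts through the seed of its guide strand, as genes with an A after the match were lower than those with another base (difference −0.31 ± 0.07, permutation p = 1e-05, the smallest that 100000 permutations give). The siRNA sequence is not given in the sources used here, so this stays a hypothesis. Of scanned genes called lower, 79.6% did not have the sequence in the longest annotated 3′ UTR. That share was not reduced for matches in the coding sequence alone, which 1206 of all scanned genes had, or for matches to part of the sequence.

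All 24 mitosis genes and 21 of 22 S phase genes fell and CCNE1 rose, while of 20 p53 targets 14 rose, CDKN1A among them, 3 fell and 3 were not called. Direct matches to all of GCCAAGT cannot be the whole cause of the fall. Of 46 mitosis and S phase members, 42 had none in the longest annotated 3′ UTR and a median of −2.64 (bootstrap SE 0.22). In any annotated transcript, 31 had none and a median of −2.62 (SE 0.19). A trend on transcript GC content and length cannot be the whole cause either. It explained 1.29% of the variance over 14650 genes and left the median at −2.63 (SE 0.17). These members were not searched for matches to part of the sequence, such as GCCAAGA, which also went with lower fold changes (z = −6.06 in the scan). The bootstrap took members as independent, although the mitosis list had an estimated correlation of 0.565. Whether the fall followed from the loss of ELN, from lowered regulators that carry the sequence, or from another effect of the siRNA or the scrambled RNA cannot be told apart. Only 1 group received an siRNA against ELN, and no second reagent, restored ELN or untreated cells were measured here. Growth itself was not measured here, so whether it slowed, and whether through ELN loss, is untested.

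The 6 libraries can be split into 3 and 3 in 10 ways. Only 1 split, the real one, gave 9838 called genes, and the highest of the others gave 0 (edgeR quasi-likelihood test, the tool run on the splits, with 102 to 313 genes at an unadjusted p under 0.05, and 10689 in the real split). These 10 splits are too few for a share under 0.05. Each of the others also put siELN and scrambled libraries on both sides, which widens the spread within a side. Their counts therefore do not show how many genes would be called without a difference.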
